A study of Mus musculus with 44 samples.

How the data were processed

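RNA was measured in blood-forming stem and progenitor cells of 22 BXD recombinant inbred mouse strains. BXD strains were inbred from the descendants of C57BL/6 and DBA/2 parents, and each strain is homozygous for its own mosaic of the parental genomes. Per the labels, the marrow of 3 female mice was pooled for each sample, and cells without lineage markers but with Sca-1 and c-kit on their surface were sorted by flow cytometry. Each strain had 2 arrays, which gave 44 arrays. The array was the Affymetrix MG_U74Av2, a one-colour oligonucleotide array on which each probe set reports the transcript it was designed for. The labels did not name the pool behind each array, so p-values measured only the spread between these arrays, which may be partly technical. The labels numbered the arrays in 2 series. Array series A held 10 strains on 20 arrays and array series B held 12 strains on 24 arrays, and no strain had arrays in both series.

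The values of the authors' deposited table were intensities on a linear scale, with 12488 probe sets per array. The 2% trimmed mean of the deposited intensities lay between 200.071 and 200.092 on every array, so each array had been scaled to a common mean before deposit. The software that summarised the probes was not given in the sources used here. The scanner parameter files were not used. No array held values identical to those of another. All columns of the table belonged to the 44 arrays.

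Intensities under 16 were set to 16 and log2 was taken. Array medians ranged from 6.55 to 6.83, a range of 0.275, which exceeded the preset limit of 0.1, so the arrays were quantile normalized. The 66 control probe sets were left out, and of the remaining 12422 those with a mean log2 value under the 40th percentile (6.00) were left out as dim, which left 7453 probe sets. A strain mean at or near the floor of 4 on the log2 scale is an upper limit of the true level, so a fold against it is a lower limit. The number of arrays limits the precision of every value. Gene symbols came from the platform's probe table and were checked through Entrez identifiers against the RefSeq gene table of GRCm38.p6, in which 10817 probe sets matched. Of the 12422 probe sets, 10833 had 1 symbol, 396 had several and 1193 had none, and genes were named only from probe sets with 1 symbol. Where a gene had several tested probe sets, the brightest over all arrays stood for it, which gave 5624 tested genes. That gene table also gave the order of genes along chromosomes. No coordinates were taken from it, because the files name no genome build.

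The strain effect was tested with limma 3.58.1 in R 4.3.3, as an F test over the 20 contrasts among strains within the array series, with 22 residual and 4.373 prior degrees of freedom. Benjamini-Hochberg adjusted p below 0.05 was the threshold throughout. Contrasts within series were used because strains were nested in series. The same fit compared each strain with the mean of the other strains of its series, adjusted within each strain. The share of variance between strains was the intraclass correlation, with a jackknife over strains as its error. It includes anything the 2 arrays of a strain shared other than genotype. Array series were compared on the 22 strain means with limma. Replicate agreement counted the arrays whose best match within the series was the other array of the strain, against 100000 random labellings.

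The 20 lists of genes were fixed before the data were examined, as were the tests, the alternatives and the rule for the genes named. The lists held stem and progenitor surface molecules, stem and progenitor transcription factors, polycomb and trithorax regulators, cell cycle genes, cell cycle inhibitors, apoptosis regulators, interferon response genes, immediate early and heat shock genes, MHC and antigen presentation genes, ribosomal proteins, oxidative phosphorylation genes, antioxidant enzymes, genes known to differ between the parents, and sex-linked controls. Further lists held markers of erythroid cells, megakaryocytes, neutrophils and monocytes, B cells, T and NK cells, and mast cells, basophils and eosinophils, which the sort could let through. Members past the strain effect were counted over all probe sets and adjusted over the list alone, with a one-sided Fisher's exact test against the other tested genes and with 10000 random lists matched on mean expression. A list score was the mean log2 value of the tested members of a list on an array, given for the 19 lists with at least 3 tested members, and was tested like a gene. Strain means of the cell cycle score were correlated with those of each other list, centred on the series mean, with 100000 permutations of strains within series.

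Pairs of genes past the strain effect were correlated over strain means by their rank distance along the chromosome, with 1000 shuffled gene orders, or 100 where all tested genes were used. Probe sets of the same gene were correlated likewise, with 10000 random pairs for comparison. For patterns with a pair of levels, the largest gap between neighbouring strain means with at least 5 strains on either side was divided by the range and set against sets of normal values. Array quality was described by the array median, the share of values at the floor, and the 3′ minus 5′ difference of the Gapdh and beta-actin control probe sets.

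The named genes were the 25 with the largest spread of strain means past the threshold, 3 higher and 3 lower genes in each of the 4 strains with the most calls, 5 higher and 5 lower genes between array series, up to 4 members of each list with the smallest adjusted p, the 5 adjacent pairs with the highest correlation, the 5 largest gap ratios, and Kit, Ly6a, Cd34, H2-Ea, Xist, Lxn and Scp2. Ly6a, which encodes Sca-1, had no probe set named for it in the probe table.

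The code was tested on simulated data with the 7453 probe sets. For the strain effect, 67.2% of changed probe sets were found at an SD between strains of 0.5 on the log2 scale and 95.5% at 1, with 7 false calls. For a single strain, 7.46% were found at a difference of 0.5, 47.8% at 1 and 93.9% at 2, with 7 false calls. For the array series, 71.6% were found at 0.5, with 4 false calls. With nothing changed, the strain effect made 1 call, and a simulated series shift gave 0 calls in the strain effect. The simulated noise was normal and independent between probe sets and arrays, with no floor and no deviation shared over an array. These rates may therefore not hold for the real arrays.

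Alternatives covered the normalization, the centring, the filter on dim probe sets, the treatment of the array series, the variance model, the Gapdh difference as a covariate, the type of probe set, the threshold, the floor, and leaving out each array and each strain in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.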

Results

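Messenger RNA levels were measured in Lin−Sca-1+c-kit+ bone marrow cells, a flow-sorted population enriched in blood-forming stem cells, from 22 BXD recombinant inbred strains with 2 arrays per strain. The study set out to find genes and chromosomal loci that control the function of these cells. Of 12422 probe sets, 7453 were bright enough to be tested. Levels are given on the log2 scale of quantile-normalized intensities, as mean ± SD over the 2 arrays of a strain, and strains were compared only within their array series, A with 10 strains or B with 12. Folds are ratios of such means and are lower limits where the lower strain lay at the floor.

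The first comparison asked which genes differed between strains. Hars, the histidyl-tRNA synthetase, ran from 4.37 ± 0.12 (SD, n = 2) in the arrays labelled BXD40 to 8.85 ± 0.31 in BXD6, a 22.4-fold range in series A, and from 4.15 ± 0.22 in BXD28 to 8.88 ± 0.82 in BXD2, a 26.4-fold range in series B (limma F test, adjusted p = 6.39e-12). Ctse, the aspartic protease cathepsin E, ranged 8.78-fold in series A, from BXD38 to BXD6, and 10.9-fold in series B, from BXD21 to BXD39 (adjusted p = 9.78e-12), by 1 of its 3 probe sets. The others did not pass (adjusted p = 0.931 and 0.474) and had r = -0.0189 and 0.170 with it. H2-Ea, which encodes the alpha chain of the class II molecule H2-E and is not transcribed from the C57BL/6 haplotype, ranged 39.7-fold from BXD8 (4.06 ± 0.08) to BXD33 (9.37 ± 0.48) and 36.3-fold from BXD2 (4.10 ± 0.14) to BXD28 (9.28 ± 0.68), with adjusted p = 2.11e-05. Hba-a1, an alpha-globin gene, ranged 18.6-fold in series A, from 7.44 ± 0.53 in BXD38 to 11.66 ± 0.05 in BXD6 (adjusted p = 1.97e-05).

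Other genes with a large spread between strains were of several kinds. Among genes of immune cells, the chemokine receptor gene Ccr2 ranged 27.5-fold in series B, from BXD19 to BXD5, and the immunoglobulin A gene Igha 12.1-fold, from BXD9 to BXD34. The cystatin gene Cst7 ranged over 3.46 on the log2 scale in series B, from BXD2 to BXD5. The class II gene H2-Aa ranged 18.3-fold in series A, from the arrays labelled BXD40 to BXD33, lay at the floor in BXD14 and reached 8.58 ± 0.52 (SD, n = 2) in BXD34, and the lipid antigen-presenting gene Cd1d2 ranged 14.9-fold in series A, from BXD6 to BXD38. Bub1, a kinase of the spindle checkpoint, ranged 21.7-fold in series B, from BXD2 to BXD14, by 1 of its probe sets, while the other did not pass (adjusted p = 0.475, r = 0.0415). Erdr1 ranged 24.5-fold, the G protein subunit gene Gnb4 19.2-fold, the angiotensin receptor-associated gene Agtrap 16.7-fold and the myosin light chain gene Myl10 15.6-fold, all in series B. Pdxdc1 ranged 22.5-fold in series B, but its other probe set did not pass (adjusted p = 0.155) and ran the opposite way over the strain means (r = -0.870). Cnn3, a calponin, lay at the floor in BXD34 and was at least 19.6-fold higher in BXD14. Vwf, the von Willebrand factor of platelets and endothelium, ranged 10.4-fold in series B, and the transcription factor gene Runx1 9.62-fold and the proteasome subunit gene Psmb6 7.33-fold in series A. Cd59a, an inhibitor of complement, ranged 10.9-fold in series A, as did the apolipoprotein gene Apoe, and Snx5, a sorting nexin, 11.4-fold in series B, while its other probe set did not pass (adjusted p = 0.196, r = -0.241). The remaining genes of the 25 were Ptprv and the probe set assigned to Mir686, with folds of 8.12 and 7.63 in series B, and AI506816, which ranged over 4.17 on the log2 scale in series A and 2.80 in series B. The other probe set of AI506816 also passed and had the opposite pattern (r = -0.532).

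In all, 209 of the 7453 probe sets (2.80%) passed the strain effect, and they stood for 146 genes. At an unadjusted p under 0.05 there were 890. The median SD between strains was 0.59 on the log2 scale among those that passed. The median intraclass correlation over all tested probe sets was 0.0386 ± 0.0373 (jackknife SE over 22 strains), against 0.00363 with no filter on dim probe sets and 0.00815 without BXD2, BXD6 and BXD34, and 358 probe sets (4.80%) had a value over 0.5. With the values of series A alone 52 probe sets passed, and 10 of 23 largest-spread genes that could be tested there lost their call, against 6 of 25 in series B alone. Without BXD2, BXD6 and BXD34, left out after the data were seen because they had the most calls, 129 passed. The call of Apoe ended when any of 22 single arrays was left out (adjusted p up to 0.122), that of Runx1 without BXD11 replicate 1 (adjusted p = 0.0513), and that of AI506816 without BXD6 replicate 2 or any array of BXD31 or BXD38 (adjusted p up to 0.0772).

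**Figure D1:**
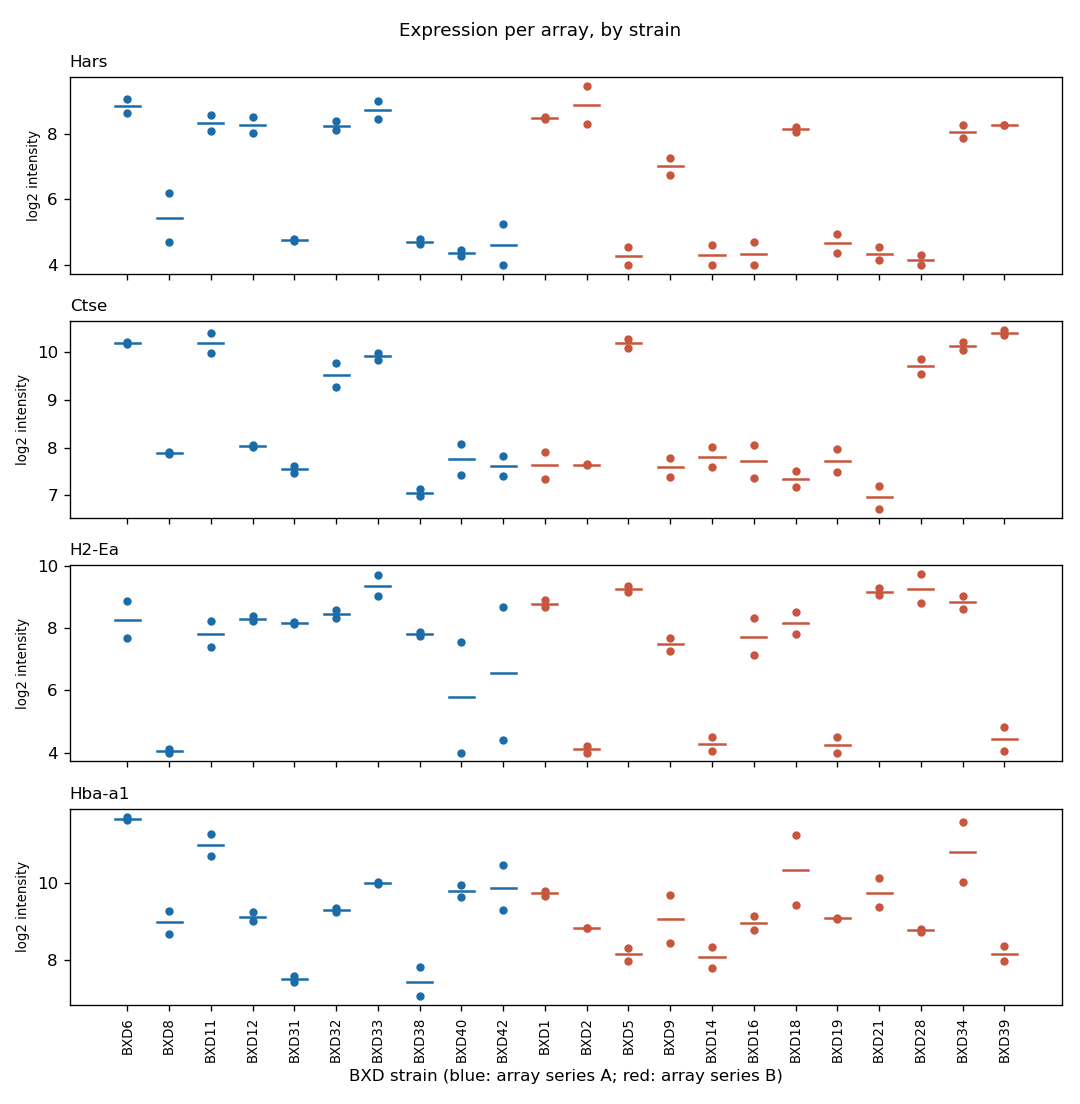
Log2 intensity (y axis) of Hars, Ctse, H2-Ea and Hba-a1 on each of the 44 arrays, by strain (x axis), with points for arrays, short lines for strain means, blue for array series A and red for series B. H2-Ea runs from 4.06 in BXD8 to 9.37 in BXD33, and the 2 arrays labelled BXD40, like the 2 labelled BXD42, lie far apart for H2-Ea.

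For 2 strains the arrays with the same label disagreed at genes whose levels separated other strains. H2-Ea was at the floor on BXD40 replicate 1 and 7.57 on replicate 2, and at 8.69 on BXD42 replicate 1 and 4.41 on replicate 2. Pdxdc1, chosen with the next genes after their values were seen, was at 9.28 and 5.46 on the arrays labelled BXD40 and at 6.21 and 9.09 on those labelled BXD42, in the same order. Erdr1 was at 11.31 and 12.92 against 12.88 and 11.12, Ccr2 at 7.08 and 8.70 against 8.83 and 7.24, and Igha at 10.49 and 8.59 against 8.68 and 10.24. Over the 272 probe sets that passed the strain effect with both strains left out, the arrays labelled BXD40 correlated at r = -0.164 and those labelled BXD42 at r = -0.111 across probe sets, which are not independent replicates. In the other 20 strains, each with probe sets chosen without it, the same r lay between 0.432 and 0.875. The labels were kept as deposited in every comparison, so values for BXD40 and BXD42 are values of arrays labelled so. With both strains left out, 272 probe sets passed the strain effect and 205 of the 209 were among them, and the single-strain calls numbered 1014 instead of 725.

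Over all 7453 tested probe sets, the other array of the same strain was the best match within the series for 11 of 44 arrays. Random labellings gave 2.10 on average and at most 14 (permutation p = 0.00013, one-sided). The median r between the arrays of a strain was 0.901 before centring on the series means, against 0.890 between strains, and 0.0843 after centring, against -0.0538. After centring, r lay below 0 in 7 of 22 strains, with the lowest value, -0.246, in the arrays labelled BXD40.

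The gene lists were examined next. The list of immediate early genes, which rise within minutes of a stimulus, and heat shock genes had the smallest p: 9 of 24 tested members passed the strain effect (Fos, Fosb, Jund, Nr4a1, Dusp1, Zfp36, Klf6, Klf4 and Jun), and 16 did when adjusted over the list alone (Fisher's exact test against 137 of 5600 other genes, adjusted p = 7.86e-08). None of its 7 heat shock genes passed by limma over all probe sets (smallest adjusted p 0.165, Hspa8), with 3 at an unadjusted p under 0.05. Hspa8 and Hspa1a were among the 16 that passed when adjusted over the list alone. Klf6, a zinc finger transcription factor, ranged 8.27-fold in series B, from 7.13 ± 0.04 (SD, n = 2) in BXD19 to 10.18 ± 0.22 in BXD1. Klf4, of the same family, ranged 7.18-fold from BXD19 to BXD2, the mRNA decay gene Zfp36 3.33-fold and the phosphatase gene Dusp1 3.09-fold. The list stayed enriched in 82 of 83 alternatives, the exception being series A alone. Fisher's test takes genes as independent, but the 9 passing members moved together across strains (median pairwise r = 0.752). The Fisher p of this list is therefore likely too small, and members of the other lists may be correlated as well. The call of Nr4a1 ended without BXD19 (adjusted p = 0.0671).

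Among markers of the sorted cells, 3 of 12 tested surface molecules passed, Flt3, Tie1 and Procr, and 7 when adjusted over the list alone (Fisher adjusted p = 0.0202, with enrichment in 24 of 83 alternatives). Procr, the endothelial protein C receptor found on stem cells, ranged 2.58-fold in series A from BXD38 to BXD33. Flt3, a receptor of early lymphoid progenitors, ranged 2.24-fold in series B from BXD34 (10.14 ± 0.35, SD, n = 2) to BXD19, while its other probe set did not pass (adjusted p = 0.833, r = 0.0599). Leaving out single arrays ended the calls of Flt3 in 31 of 44 fits (adjusted p up to 0.106) and of Tie1 in 23 (up to 0.103). Cd48, a marker of progenitors, did not pass (adjusted p = 0.153) but did without BXD11 replicate 1 (0.000315), without strain BXD11 (0.0481) and with the Gapdh covariate (0.0392). Kit, the receptor c-kit that defined the sort, did not pass (SD between strains 0.25, adjusted p = 0.826), nor did Cd34 (SD 0.25, adjusted p = 0.757). Of 19 stem and progenitor transcription factors, 3 passed, Zfpm1, Runx1 and Fli1, and 5 when adjusted over the list alone (Fisher adjusted p = 0.0369, with enrichment in 35 of 83 alternatives). Fli1, an ETS factor, ranged 6.82-fold in series A from BXD12 to BXD32, and Zfpm1, the cofactor of GATA1, 2.81-fold from BXD38 to BXD11. Gfi1 did not pass (adjusted p = 0.156) except without BXD16 replicate 1 (0.0376) and with the Gapdh covariate (0.0349), and the call of Zfpm1 ended without any of 26 single arrays (up to 0.109). Lxn and Scp2 did not pass, with adjusted p of 0.253 and 0.829.

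Markers of other blood cells also differed between strains. Of 14 neutrophil and monocyte markers, 4 passed (Camp, S100a8, S100a9 and Mpo), and 5 when adjusted over the list alone (Fisher adjusted p = 0.00356, 76 of 83 alternatives). A dimmer probe set of Lcn2 also passed by limma (adjusted p = 0.0426), while its brightest did not (0.975). Camp, an antimicrobial peptide of neutrophil granules, reached 12.47 ± 0.20 (SD, n = 2) in BXD32, 3.20-fold above BXD38. S100a8 and S100a9, which encode the subunits of calprotectin, ranged 2.98-fold and 2.41-fold in series A, and the myeloperoxidase gene Mpo 9.60-fold in series B, from BXD34 to BXD21. The call of Camp ended without BXD32 replicate 2 (adjusted p = 0.0582), that of S100a8 without BXD32 replicate 1 (0.0650), that of S100a9 without BXD2 replicate 2 (0.0800) or BXD38 replicate 2 (0.0651), and that of Mpo without any of 20 single arrays (up to 0.118). Of 13 B cell markers, 3 passed (Dntt, Ighm and Jchain), and 4 when adjusted over the list alone (Fisher adjusted p = 0.0202, 74 of 83 alternatives). Dntt, the terminal transferase of lymphoid progenitors, was 3.64-fold higher in BXD16 than in BXD34, and Ighm, the mu heavy chain, 6.74-fold higher in BXD6 than in BXD8. A further probe set of Ighm passed (r = 0.233 with the first) and another did not (adjusted p = 0.358). Jchain ranged 4.11-fold in series B from BXD21 to BXD14, and its call ended without either BXD14 array (adjusted p = 0.0647 and 0.0684). Of 7 erythroid markers, Hba-a1 passed, alone also when adjusted over the list alone, while Gata1 (adjusted p = 0.264), Slc4a1 (0.578) and Klf1 (0.851) did not. Of 4 megakaryocyte markers, Vwf passed, and 2 did when adjusted over the list alone, with Nfe2 at adjusted p = 0.0596. None of 9 T and NK cell markers passed by limma or by the ordinary F test, with 0 adjusted over the list alone, 2 at an unadjusted p under 0.05 and a smallest adjusted p of 0.176 for Il7r. Il7r passed in series B alone (0.0405), with the series not modelled (0.0449) and without BXD40 and BXD42 (0.0493). None of 3 mast cell, basophil and eosinophil markers passed by either test, with 0 adjusted over the list alone and 1 at an unadjusted p under 0.05. Cpa3, a mast cell protease, had an adjusted p of 0.304, and 0.0298 without BXD11 replicate 1. Nfe2 passed in 11 of 82 alternatives, among them those without 1 of 2 single arrays (adjusted p down to 0.0282).

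In the remaining lists, 3 of 19 MHC and antigen presentation genes passed (Tap2, H2-Ea and H2-Aa), and 4 when adjusted over the list alone (Fisher adjusted p = 0.0369, 51 of 83 alternatives). Tap2, a peptide transporter subunit, ranged 2.63-fold in series B from BXD16 to BXD2, and its call ended without BXD2 (adjusted p = 0.0776). Of 17 interferon response genes, 2 passed, Iigp1 and Rsad2, and 5 when adjusted over the list alone (Fisher adjusted p = 0.176). Rsad2, the antiviral protein viperin, was 10.1-fold higher in BXD5 than in BXD2, and the GTPase gene Iigp1 3.74-fold higher in BXD5 than in BXD19. The call of Rsad2 ended without BXD2 replicate 1 (adjusted p = 0.0724) or BXD5 replicate 2 (0.0504), and that of Iigp1 without any array of BXD5, BXD19 or BXD32 (up to 0.113). Of 7 genes known to differ in sequence or copy number between the parents, H2-Ea and Nnt passed, and 4 did when adjusted over the list alone (Fisher adjusted p = 0.0369, 53 of 83 alternatives). Nnt, the mitochondrial transhydrogenase that carries a deletion in the C57BL/6J substrain, lay at the floor in BXD38 and was at least 11.3-fold higher in BXD8. Its call ended without either BXD38 array, BXD34 replicate 1 or BXD12 replicate 1 (adjusted p between 0.0503 and 0.132). Of 30 cell cycle genes Bub1 passed, and 2 did when adjusted over the list alone, with Top2a at adjusted p = 0.0504, and below the threshold in 21 of 82 alternatives, 9 of them without a single array. Of 13 cell cycle inhibitors the antiproliferative gene Btg2 passed, with a 2.48-fold range in series B, and 4 did when adjusted over the list alone. None of 14 polycomb and trithorax regulators (smallest adjusted p 0.439, Ring1), 16 apoptosis regulators (0.178, Mcl1), 19 ribosomal protein genes (0.0613, Rpsa), 34 oxidative phosphorylation genes (0.227, Uqcrc2) or 25 antioxidant enzymes (0.0692, Gclm) passed by limma. Adjusted over the list alone, 1 ribosomal gene passed and 0 of the others. At an unadjusted p under 0.05 there were 0, 1, 3, 3 and 3 in these lists, and by the ordinary F test 1 ribosomal gene passed and 0 of the others. In the alternatives Rpsa passed in 13 (down to 0.0120), Gclm in 7 (down to 0.0148), Mcl1 without BXD28 replicate 1 (0.0389) and with the series not modelled (0.0449), and Ring1 with the series not modelled (0.0355). These counts took each gene by its brightest probe set. A dimmer one passed for the antioxidant enzyme Glo1 (adjusted p = 0.0373), H2-D1 of the MHC list (0.000167) and Ifi204 of the interferon list (0.00845). Their brightest probe sets did not pass (0.546, 0.178 and 0.943). Xist, the X-inactivation RNA expressed in female cells, averaged 11.07 over all arrays and did not pass (adjusted p = 0.284), though it did adjusted over the list alone, as its only tested member. Enrichment passed for 7 lists in all, and for 0 in series A alone, 2 in series B alone and 3 with the values as deposited.

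List scores, the mean over the members of a list, were compared between each strain and the rest of its series. Interferon response genes were higher in BXD5 by 0.63 ± 0.07 (SE, log2), with 16 of 17 members above the rest of the series (limma, adjusted p = 2.72e-07), and in BXD28 by 0.25. They were lower in the arrays labelled BXD42 (-0.32), in BXD34 (-0.24), in BXD2 (-0.23) and in BXD9 (-0.21). The immediate early and heat shock score was lower in BXD19 by -0.67 ± 0.08 (adjusted p = 6.91e-07), with 6 of 24 members above the rest, and higher in BXD1 (0.47, 21 of 24 members), BXD2 (0.43) and BXD34 (0.33). It was also lower in BXD28, BXD39 and BXD12. In a split of the list made after its results were seen, the 7 heat shock genes did not differ in BXD19 (0.14, adjusted p = 0.616), BXD2 (0.07) or BXD34 (-0.22) and were higher in BXD1 (0.53, adjusted p = 0.0175) and BXD8 (0.47, adjusted p = 0.0370). The mean of the other 17 members was lower in BXD19 (adjusted p = 3.06e-09).

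The erythroid score was lower in BXD38 (-0.55 ± 0.08, adjusted p = 1.91e-05, 2 of 7 members above the rest), BXD31 (2 of 7), BXD39 (0 of 7) and BXD5 (1 of 7), and higher in BXD34 (0.48, 7 of 7 members) and BXD11 (5 of 7). In BXD6 it was higher by 0.24 (adjusted p = 0.0475) with 3 of 7 members above the rest, and this call was lost in 48 of 80 alternatives. Much of these scores came from Hba-a1. Without it the score stayed lower in BXD38 (-0.27, adjusted p = 0.0228) and higher in BXD34 (0.26, adjusted p = 0.0246), but the calls in BXD31 (-0.08, adjusted p = 0.585), BXD39 (-0.18), BXD5 (-0.16) and BXD11 (0.04) ended, and in BXD6 the difference was -0.13 (adjusted p = 0.350). The score of 4 megakaryocyte markers was higher in BXD9 (0.81 ± 0.17, 4 of 4 members above the rest), BXD34 (4 of 4) and BXD11 (3 of 4), and lower in BXD6 (1 of 4), BXD32 (0 of 4) and BXD39 (1 of 4). Without Vwf only the call in BXD9 remained (0.52, adjusted p = 0.00876), and the score over all strains did not pass (adjusted p = 0.0572). The calls in BXD11 and BXD39 were lost in 45 and 40 of 80 alternatives.

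Cell cycle genes were lower in BXD2 by -0.48 ± 0.10 (SE, log2; adjusted p = 0.00167) and in BXD34 by -0.41 ± 0.10 (adjusted p = 0.00484), with 4 of 30 members above the rest in each. Neutrophil and monocyte markers were higher in BXD2 (0.40, 11 of 14 members) and BXD32 (0.34, 11 of 14). The B cell score was higher in BXD14 (0.39) and BXD6 (0.32), and without Ighm in BXD14 (0.29, adjusted p = 0.0140) but not BXD6 (0.16, adjusted p = 0.233), nor over all strains (adjusted p = 0.0641). The MHC score was higher in BXD33 (0.45) and lower in BXD19 (-0.38) and BXD14 (-0.37), where 7 and 8 of 19 members were still above the rest and the calls ended without H2-Ea (adjusted p = 0.107 and 0.119). Oxidative phosphorylation genes were higher in the arrays labelled BXD42 (0.26) and in BXD18 (0.22, lost in 32 of 81 alternatives) and lower in BXD11 (-0.24), and stem and progenitor transcription factors were higher in BXD31 and BXD33 and lower in the arrays labelled BXD40. Leaving out Fli1 ended the calls of that list in BXD31 (adjusted p = 0.131) and the arrays labelled BXD40 (0.105), and leaving out Rsad2 those of the interferon list in BXD2 (0.338) and BXD28 (0.0522). Of the 418 pairs of a strain and a list, 49 passed. Of these, 30 lost their call when some single member of the list was left out. The score of genes known to differ between the parents passed in 8 strains, and every one of these calls ended without 1 gene, H2-Ea in 7 strains and Nnt in BXD38. Over all strains, 11 of 19 scores passed the F test, with the interferon (adjusted p = 1.85e-06) and immediate early scores (2.87e-07) among the strongest, and 5 did in series A alone. Surface molecules, polycomb and trithorax regulators, cell cycle inhibitors, apoptosis regulators, T and NK cell markers, mast cell markers, ribosomal proteins and antioxidant enzymes did not pass, with adjusted p from 0.0805 to 0.784.

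The F test calls of some list scores changed in the alternatives. The oxidative phosphorylation score lost its call (main adjusted p = 0.0288) without BXD40 and BXD42 (0.0995), without either array labelled BXD42 (0.0775 and 0.0522) and without BXD11 replicate 2 (0.0730). It also lost it without strain BXD11 (0.0814) or BXD42 (0.101), in series A (0.0600) or series B alone (0.378), with suffixed probe sets left out (0.287) and with array medians set equal (0.0574). The neutrophil and monocyte score lost its call (main 0.0107) without BXD2 replicate 2 (0.0536), without strain BXD2 (0.127) or BXD32 (0.0623), without BXD2, BXD6 and BXD34 (0.0552) and in series A alone (0.180). The immediate early score did not pass in series A alone (adjusted p = 0.180), where only BXD12 had been called, and neither did the cell cycle (0.261), B cell (0.261) and MHC scores (0.197). The transcription factor score did not pass in series B alone (0.378). The cell cycle score also lost its call without BXD2, BXD6 and BXD34 (0.135). The mast cell score passed without any of 4 single arrays (down to 0.0206) and the ribosomal score without BXD18 replicate 2 (0.0287).

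The strain and list pairs that kept their call with any single array left out were immediate early genes in BXD1, BXD2 and BXD19, interferon genes in BXD5 and the arrays labelled BXD42, erythroid markers in BXD31, BXD34 and BXD38, cell cycle genes and neutrophil markers in BXD2, B cell markers in BXD14, megakaryocyte markers in BXD9, and genes known to differ between the parents in BXD19. The other pairs that passed lost their call without at least 1 array. Those of erythroid markers in BXD31 and of genes known to differ between the parents in BXD19 ended without 1 member, Hba-a1 and H2-Ea.

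**Figure D2:**
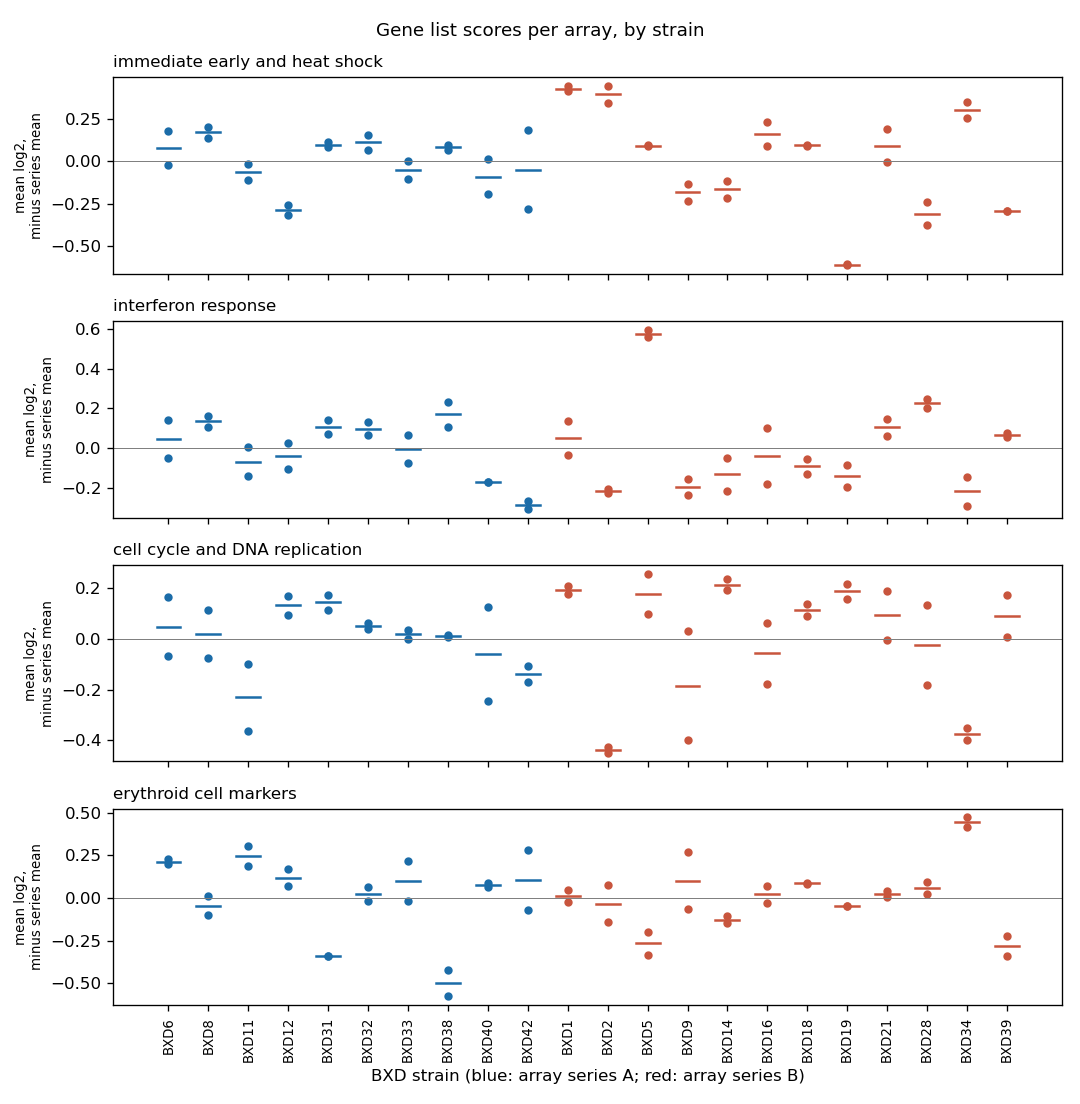
Mean log2 value of list members on each array minus the series mean (y axis), by strain (x axis), for 4 gene lists, with points for arrays and short lines for strain means, blue for array series A and red for series B. Immediate early and heat shock genes lie lowest in BXD19 (-0.67 against the rest of the series), interferon response genes highest in BXD5 (0.63).

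Strains differed in how many probe sets set them apart from the rest of their series. BXD2 had 126 (59 higher, 67 lower), BXD6 111 (46 and 65), BXD34 83 (40 and 43) and BXD11 53 (20 and 33). Of these, 61, 41, 55 and 34 also passed the strain effect. Over all strains, 414 probe sets were called in some strain, and 174 of them passed the strain effect. In BXD2, the myosin light chain gene Myl10 was 5.20-fold higher (8.64 ± 0.36, SD, n = 2, against 6.26 ± 1.17 over 11 strains) and Cst7 5.53-fold lower. Of 14 tested neutrophil and monocyte markers, Camp, S100a9, Ltf and Lyz2 were called higher in BXD2 and 0 lower. Of 30 cell cycle genes, Ccnb2, Mad2l1, Aurka and Bub1 were called lower and 0 higher. Among these, only Camp, S100a9 and Bub1 also passed the strain effect. In BXD6, Hba-a1 was 5.42-fold higher (11.66 ± 0.05 against 9.22 ± 1.15 over 9 strains; limma, adjusted p = 0.000407), and Dbi, an acyl-CoA-binding protein, 4.87-fold lower. In BXD34, Ctse was 3.68-fold higher, while Nnt was 4.88-fold and the interferon-inducible gene Ifi27 4.44-fold lower. In BXD11, Cd244a, a receptor of natural killer and progenitor cells, lay at the floor and was at least 5.48-fold lower, and Runx1 was 5.39-fold lower.

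Hars was higher in all 4 of these strains, by 7.32-fold in BXD2, 5.52-fold in BXD6, 3.98-fold in BXD34 and 3.71-fold in BXD11. This was not particular to them, since its strain means split into 11 low and 11 high. Hars was also called higher in BXD12, BXD33, BXD32, BXD18, BXD39 and BXD1. Cnn3 was 5.03-fold lower in BXD2 and at least 5.70-fold lower in BXD34, and H2-Ea differed by -3.33 ± 0.64 (SE, log2) in BXD2. In BXD2 Agtrap was 4.37-fold higher, in BXD34 Pdxdc1 4.73-fold, in BXD6 AI506816 4.47-fold, and in BXD11 Ctse 3.46-fold and Hba-a1 3.20-fold. Lower genes were the tRNA exportin gene Xpot (5.52-fold) and Cd1d2 (4.66-fold) in BXD6 and Ifi27 (3.34-fold) in BXD11. With 1 array of the strain left out, the call of H2-Ea in BXD2 ended without either array (adjusted p up to 0.139), of Nnt without BXD34 replicate 1 (0.443), of Hars in BXD11 without replicate 1 (0.0746), of Runx1 without either BXD11 array (up to 0.235) of Myl10 without BXD2 replicate 2 (0.0960), of Dbi without BXD6 replicate 1 (0.0828), and of Ifi27 in BXD34 without either array (up to 0.121). Those of Xpot and Cd1d2 in BXD6 and of Hba-a1 in BXD11 ended without either array (up to 0.203, 0.277 and 0.236). Agtrap, Pdxdc1, AI506816 and Ifi27 in BXD11 lost their calls in 44, 56, 44 and 58 alternatives.

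Over all strains there were 725 calls, 277 higher and 448 lower, against 548 higher and 483 lower with no filter on dim probe sets, with a median of 21 per strain and a low of 4 in the arrays labelled BXD40. With its replicate 1 or 2 left out, BXD2 had 79 or 22 calls, BXD34 42 or 62 and BXD11 60 or 10. With 1 array left in a strain, the spread came from the other strains, and the calls of such a strain ranged from 0 to 465. With BXD16 replicate 1 left out the total was 1199, of which 465 were in BXD16 itself against 24 with both arrays.

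**Figure D3:**
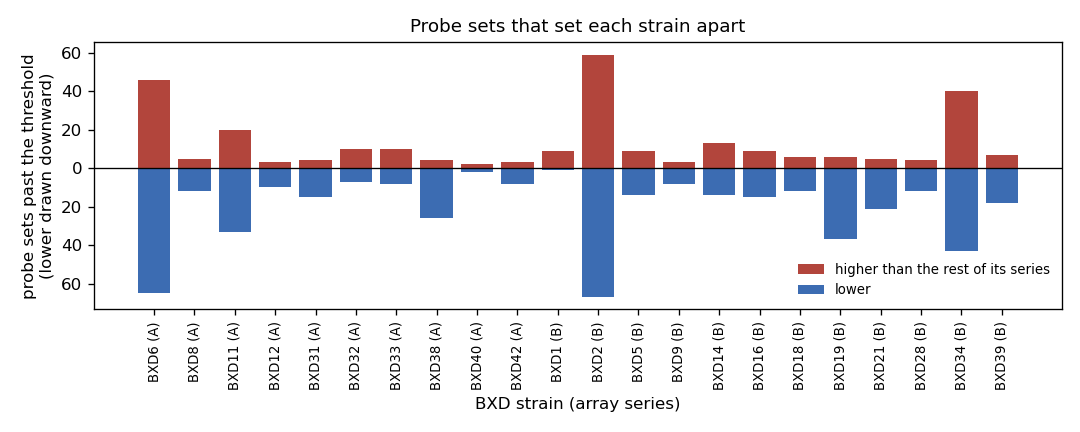
Number of probe sets past the threshold in each strain against the rest of its array series (y axis), by strain (x axis), with probe sets higher in the strain drawn upward in red and those lower drawn downward in blue. BXD2 (126), BXD6 (111) and BXD34 (83) have the most, the arrays labelled BXD40 the fewest (4).

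The series were compared as a technical check. Snx5 was 3.86-fold higher in series B (7.51 ± 1.21, SD over n = 12 strains) than in series A (5.56 ± 1.03, n = 10), Ptbp2, a splicing regulator, 3.14-fold, Egln1, an oxygen-sensing prolyl hydroxylase, 3.13-fold, AI506816 2.92-fold and the immediate early gene Nr4a1 2.83-fold. Lower in series B were Cpsf4, an mRNA cleavage factor, by 2.62-fold, Col7a1, a collagen, by 2.39-fold, Igha by 2.35-fold, AU021092 by 2.26-fold and Tmem37 by 2.25-fold. In all 1628 probe sets (21.8%) passed by limma on strain means, 802 higher and 826 lower in series B. Because each strain lay in 1 series, these values hold the difference between the strain sets as well as that between the series. With array medians set equal 2039 passed, and 28.4% of them were higher in series B instead of 49.3%. With the values as deposited 54.7% were. The call of Igha ended in 12 of 24 alternatives.

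Whether gene groups moved together across strains was examined for the cell cycle score against 18 others. It correlated with the polycomb and trithorax score (r = 0.685, permutation p = 0.00175, rho = 0.695, p = 0.0012, 22 strain means, adjusted p = 0.0315). The polycomb and trithorax score itself did not differ between strains (limma F test, adjusted p = 0.665, intraclass correlation -0.105). The correlation may therefore reflect spread shared by the scores on single arrays, and not strain differences. Without BXD2 and BXD34, the strains farthest out, r was 0.547 (permutation p = 0.0178), which no longer passed after adjustment, and neither did r with the series mean not subtracted (0.563). Within series B r was 0.767 (permutation p = 0.00334, n = 12) and within series A 0.365 (permutation p = 0.301, n = 10). No other relation passed, the next being with megakaryocyte markers (r = -0.512, permutation p = 0.0140, adjusted p = 0.107) and erythroid markers (r = -0.475, permutation p = 0.0178, adjusted p = 0.107).

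Genes that lie near each other are inherited together in such strains, so their strain patterns were compared. Among adjacent genes that both passed the strain effect, S100a8 and S100a9 had r = 0.725 and Mpo and Dynll2, a dynein light chain gene, r = -0.583 over 22 strain means, the adhesion receptor genes Adgrg1 and Adgrg3 r = -0.386, Ctla2b and Fbp1 r = 0.179 (the call of Fbp1 was lost in 28 of 82 alternatives), and Tap2 and H2-Aa r = 0.106. H2-Ea and H2-Aa, a pair at rank distance 2 chosen after its value was seen, had r = 0.719. The median absolute r was 0.179 over 7 adjacent pairs (permutation p = 0.588), 0.381 over 11 pairs at a rank distance of 2 to 5 (p = 0.00699), 0.403 over 54 pairs at 6 to 20 and 0.242 over 232 pairs at 21 to 100, both with p = 0.001, the smallest that 1000 shuffled orders can give. It was 0.187 beyond 100 genes and 0.192 for pairs on other chromosomes. With the strains of series A alone, permutation p was 0.245 at 2 to 5, 0.002 at 6 to 20 and 0.314 at 21 to 100. These are relations across genes, which are not independent replicates. Over all tested genes, the medians lay close to those of 100 shuffled orders. They were 0.1914 against 0.1862 at 1 and 0.1872 against 0.1865 at 21 to 100, both with permutation p = 0.0297. At 2 to 5 (0.188, permutation p = 0.188) and 6 to 20 (0.187, p = 0.119) p was larger. The permutation p of the distance classes were not adjusted.

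**Figure D4:**
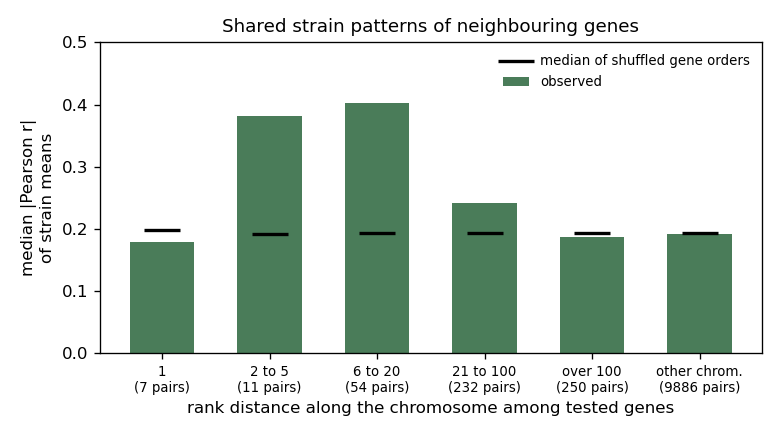
Median absolute Pearson r of strain means (y axis) between genes past the strain effect, by rank distance along the chromosome (x axis, with the number of pairs), with bars for observed values and black marks for the median of shuffled gene orders. The bars at 2 to 5 (0.381) and 6 to 20 (0.403) stand above their marks (0.191 and 0.194).

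Strain means of some genes fell into a pair of levels. The largest gaps relative to the range were those of the probe set assigned to Mir686 (0.545 of the range, with 16 strains below and 6 above), Spg21, a gene linked to hereditary spastic paraplegia (0.516, 17 and 5), Ctse (0.427, 14 and 8), Hars (0.399, 11 and 11) and Gnb4 (0.385, 7 and 15). Of the 209 probe sets past the strain effect, 38 (18.2%) exceeded the gap expected in 5% of sets of normal values (exact binomial p = 5.68e-12, across probe sets, which are not independent).

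A further comparison asked whether another probe set of the same gene showed the same strain pattern. In 53 pairs with at least 1 probe set past the strain effect the median r over 22 strain means was 0.201, against -0.00885 in random pairs, and 19 pairs exceeded the 95th percentile of random pairs. The median was 0.528 in the 5 pairs where both passed and 0.163 in the 48 where 1 did.

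Array quality differed little between strains within a series. Between series, array medians as deposited averaged 6.63 ± 0.04 (SD, log2, n = 20) in A and 6.72 ± 0.04 (n = 24) in B. The share of values at the floor averaged 15.1% in A and 13.9% in B. The Gapdh 3′ minus 5′ difference, which grows as RNA or its copies shorten, averaged 3.50 ± 0.37 (SD, log2, n = 44) and did not differ between strains (permutation p = 0.966), nor did the beta-actin difference (4.07 ± 0.42, permutation p = 0.0740). The Gapdh difference was higher on the odd-numbered than on the even-numbered array in 20 of 22 strains, by 0.46 ± 0.43 on average (permutation p = 0.00015), a contrast chosen after the values were seen. With the Gapdh difference as a covariate, the median intraclass correlation was 0.0811 instead of 0.0386, and with a term for odd against even array numbers 0.0719.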

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

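Chosen after results were seen were the fits without BXD2, BXD6 and BXD34, without BXD40 and BXD42, with a replicate block (odd and even array numbers as a term), with the Gapdh difference per strain, and with the widest member left out of each list. No single-strain call of a named gene or list turned direction except the erythroid score in BXD6 without Hba-a1, but single-strain calls went from 277 higher and 448 lower to 548 and 483 with no filter, and the share higher in series B from 49.3% to 54.7% with values as deposited. The strain effect (209 probe sets) moved to 483 with the series not modelled, 52 in series A alone, 127 at adjusted p below 0.01 and 129 without BXD2, BXD6 and BXD34, of which 120 were among the 209. The median intraclass correlation (0.0386) moved to 0.113 with the series not modelled, 0.0811 with the Gapdh covariate, 0.0719 with the replicate block, 0.00815 without BXD2, BXD6 and BXD34 and 0.00363 with no filter. Single-strain calls (725) moved to 1143 with the series not modelled, 126 in series A alone, 424 in series B alone, 338 at 0.01 and 398 without BXD2, BXD6 and BXD34. Scores past the F test (11) numbered 5 in series A alone and 9 with the widest member left out of each list. Enriched lists (7) numbered 3 with values as deposited, 4 with no filter, 4 above the 60th percentile, 3 with the series not modelled, 0 in series A alone, 2 in series B alone, 3 with the ordinary F test, 4 with suffixed probe sets left out, 1 at 0.01 and 2 without BXD2, BXD6 and BXD34. The array series difference (1628) moved to 772 at 0.01. Arrays matched to their strain (11) numbered 5 in series A alone and 6 in series B alone. Matches were sought within the series in the main count too, so these are parts of it and not a drop. Between neighbouring genes, series A alone gave 0.329 (permutation p = 0.245) at 2 to 5 and 0.277 (p = 0.314) at 21 to 100, and all tested genes gave 0.191 (p = 0.0297) at 1, 0.188 (p = 0.188) at 2 to 5 and 0.187 (p = 0.119) at 6 to 20. Sibling probe sets that both passed had r = 0.528. Score correlations past the threshold (1) numbered 0 with the series mean not subtracted and 0 without the farthest strains. A stricter threshold accounts by construction for the lower counts at 0.01. Single-strain calls are summed over strains, so a fit without some strains lacks the calls of those strains. In the main fit BXD2, BXD6 and BXD34 had 126, 111 and 83 of the 725. Elsewhere the cause was not tested. Fewer strains need not lower the strain effect count, as 272 probe sets passed it without BXD40 and BXD42. With 1 array left out, the strain effect ranged from 171 to 247, the intraclass correlation from 0.0199 to 0.0873 (without BXD16 replicate 1), single-strain calls from 593 to 1199 (without BXD16 replicate 1), enriched lists from 2 to 7 and scores from 10 to 12. With 1 strain left out they ranged from 171 to 235, 0.0244 to 0.0546, 588 to 844, 2 to 8 and 10 to 11, and the series difference from 1431 to 1672. Of the values of named genes, 8890 kept their side of the threshold, 127 gained a call and 328 lost it. The replicate block gave 232 probe sets, 826 single-strain calls, 11 scores and 8 enriched lists. Odd and even arrays differed at 31 probe sets, but not alike in every strain: the odd minus even differences had r over 0.1 in 19 of 45 pairs of strains in series A (median 0.0616) and 25 of 66 in series B (median 0.0839). Near the floor, which held 9.32% to 18.1% of values per array, folds are lower limits.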

Other observations

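Tests chosen after the results were seen were the odd and even comparison, all tests of the arrays labelled BXD40 and BXD42, the test of shared handling and the test of a variant under the probes.

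Odd-numbered and even-numbered arrays of a strain differed at 31 probe sets, 24 of them higher on odd arrays (limma, 1354 at an unadjusted p under 0.05). Plod3, a lysyl hydroxylase, was higher on the odd array by 0.56 ± 0.09 (SE, log2) in 21 of 22 strains, and the translation factor gene Eif3c by 0.65 ± 0.11 in 20. Ranbp1, a partner of the GTPase Ran, differed by -0.50 ± 0.09 and was higher on the odd array in 1 of 22 strains.

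As many probe sets as the 209 of the strain effect were found in 1 of 100 assignments of arrays to strains, the real one, and the highest other gave 24. For the array series, 1 of 100 splits of the strains, the real one, gave as many as 1628, and the highest other gave 38. Chance assignment is excluded for both.

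The score of immediate early and heat shock genes differed between strains. None of the 7 heat shock genes passed alone over all probe sets. In the split made after results were seen, their mean did differ between strains (limma F test, adjusted p = 0.0290). Cells of another lineage stay open. The score still differed with 6 lineage scores as covariates (limma F test, adjusted p = 4.27e-09). However, that fit took the covariate slopes only from differences between the 2 arrays of a strain. It may therefore not remove a cell mix that both arrays of a strain shared. The SD of the score between strains was 0.251 without and 0.288 with the covariates. Separate local variants at each gene are argued against by a median pairwise r of 0.752 among the 9 passing members, above the upper limit of random sets of passing genes, 0.160. Handling shared by both arrays of a strain cannot be told apart from a difference between strains, because either could give the intraclass correlation of 0.848 and the labels do not say when or how each pool was sorted. A strain difference stays open and untested.

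In 48 pairs of probe sets of a gene, 1 passed the strain effect and the other did not. The strain patterns were not always unlike, since r was above 0.5 in 14 of these pairs and below 0 in 14. A strain variant under the probes stays open. The median r of 0.163 in 48 such pairs exceeded the upper limit for medians of random pairs, 0.0823. This cannot decide the question, because a variant under probes shared by both probe sets would move both. Whether probe sets of a pair shared probes was not examined. Some probe sets also entered several pairs, unlike in the random pairs. A dim partner probe set stays open (rho = 0.217 with the partner's level, permutation p = 0.137).

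The arrays labelled BXD40 disagreed with each other, as did those labelled BXD42. Poor arrays are argued against by the crossed pairs, which correlated at 0.615 and 0.502, within the range of the other strains. A segment still segregating within a strain is argued against by same-strain r of -0.164 and -0.111 over probe sets chosen without these strains. Mislabelled arrays are a candidate explanation. Exchanging 1 array of each gave 312 probe sets past the strain effect against 209 as labelled. The highest of the other exchanges in series A, between BXD33 and BXD42, gave 252. Of 90 exchanges, 5 gave more than 209. By the median intraclass correlation the exchange of BXD40 and BXD42 did not rank first (0.0682, against 0.0956 for BXD33 and BXD42). Which arrays would carry the right label is not settled, and no biological explanation other than a segregating segment was tested.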
